A study of Mus musculus with 4 samples.

How the data were processed

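Chromatin immunoprecipitation followed by sequencing was carried out on V6.5 mouse embryonic stem cells, a line of mixed C57BL/6 and 129 background, with antibodies against REST, Ring1b, MCAF1 and H4K20me3. Per the labels' protocols, cells were moved off their feeder layer for 1 passage before the REST experiment and for 2 passages before the others. Sonicated chromatin had a mean fragment length of 500 bp, ligated DNA was amplified over 18 cycles, and a gel slice of 150 to 300 bp (Ring1b and MCAF1) or 150 to 350 bp (REST and H4K20me3) was cut, which the protocols equate with inserts of 50 to 200 nt. Each antibody was represented by 1 library, and the labels place each library on a flow cell of its own. Antibody, sequencing run and replicate therefore cannot be separated, and no difference between antibodies had a replicate check. No input or control antibody library was used here.

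The deposited values are signed read positions, 1 entry per reported alignment, with a minus sign for the minus strand; they are not normalised and are not counts per feature. Per the file headers and the submitters' processing notes, reads were aligned with Bowtie to the mm8 assembly of the mouse genome; the version is not given in the sources used here. Per the file headers, up to 2 locations were reported per read, reads with more than 2 were dropped, 2 seed mismatches and a mismatch quality sum of 70 were allowed, and the best alignments were requested. The seed was 26 bases for REST and Ring1b and 36 bases for MCAF1 and H4K20me3, per the file headers. Reads with 1 reported location were analysed. Reads with 2 locations, which made up 3.32% to 6.43% of aligned reads, entered an alternative chosen after the data were examined. The lowest nuclear position of 3000000 in 3 libraries follows the unsequenced start of mouse chromosomes and was read as counting from 0; coordinates below were converted to count from 1. Whether a minus-strand position marks the leftmost or the 5′ base of a read is not given in the sources used here.

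At each position and strand 1 read was kept, and reads were moved 75 bp towards their 3′ end. Read numbers were taken in windows of 1000 bp every 500 bp. A window was covered if it held a read of any library; 4598722 of 5261489 windows (87.4%) were covered. A window was enriched when the Poisson upper-tail probability of its read number was at most 1e-09 and the number was at least 5 times background, which was the larger of the mean over covered windows of the genome and the mean over the surrounding 1 Mb. Enriched windows that overlapped were joined into regions, and regions within 10 kb of each other into domains. A fold is the read number of the highest window over its background for a named region, or the read density over all covered sequence of the library for a set of regions or a domain. This test sets reads against the background inside 1 library and does not compare antibodies. Mitochondrial reads were left out of the region calls.

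Regions were counted as shared if they overlapped by at least 1 bp, and regions called in all 4 libraries were left out of the pair counts. Shared counts were set beside 1000 circular shifts of a region set along the covered windows of each chromosome. The shifts preserve the spacing of regions, but not base composition, chromatin openness, repeat content or a background that both libraries of a pair share. For 3 pairs called against the 2 outside libraries, reads were therefore also divided at random into 2 equal parts. Shared regions were called from 1 part, at the square root of the probability threshold, and the folds of both libraries relative to the pooled outside libraries were counted in the other part, with an outside count of 0 set to 1 read. Similarity across the genome was the Spearman correlation of read numbers in 10 kb bins, which are not independent replicates. The number of identical read positions that would follow from molecules carried between libraries was taken from the enriched reads of a pair and the part of each library that was sequenced, estimated from its repeated positions at 24.2% for REST, 12.4% for Ring1b, 23.4% for MCAF1 and 4.10% for H4K20me3; unequal amplification would change these estimates. Intervals are exact 95% intervals, Clopper-Pearson for shares and Poisson for read numbers; they cover counting error only, since amplified reads are not independent molecules. The named regions were fixed before the data were examined: the 10 regions with the highest fold in each library outside those called in all 4, the 3 shared regions of each pair with the highest smaller fold, the 3 widest domains per library and the 3 regions called in all 4 libraries that were highest by the smallest of the 4 folds. The text gives examples from most of these groups. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

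The detection step was tested on simulated data, with 50 regions of each size planted at each library's own background. At 10 times background, 58% of planted regions were found for REST, 60% for Ring1b, 100% for MCAF1 and 98% for H4K20me3; at 5 times background the shares were 2%, 6%, 28% and 40%. At 20 times background at least 98% were found in each library. No call was made elsewhere among 4598722 simulated windows per library. The simulated reads followed the Poisson distribution that the call assumes, so this outcome was largely fixed in advance. In the real libraries the variance of window counts was 4.12 (REST) to 17.3 (Ring1b) times the mean, and the rate of false calls there was not measured. In an average covered window, 14 reads were needed for a call in REST and Ring1b (10.3-fold and 10.4-fold), 24 in MCAF1 (5.01-fold) and 20 in H4K20me3 (5.91-fold). Region numbers between libraries therefore reflect depth as well as enrichment.

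Alternatives covered the treatment of repeated positions, the probability threshold, the fold minimum, the window size, the read shift, the background, depth, the overlap rule, bin size and merging distance. The use of the other 3 libraries as background was among them. A background from the 2 libraries outside a pair, and groups of regions by density over the genome mean in place of fold over the local background, were added after the data were examined. An annotation of mm8 was not used here, so regions are given by coordinates without gene names, and 9 gene lists fixed beforehand were not compared.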

Results

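The locations of 3 chromatin regulators and 1 histone mark were mapped in mouse embryonic stem cells. REST is a DNA-binding repressor of neuronal genes, Ring1b is the ubiquitin ligase of Polycomb repressive complex 1, and MCAF1, also called ATF7IP, is a partner of the histone methyltransferase SETDB1. H4K20me3, trimethylated lysine 20 of histone H4, is a mark of constitutive heterochromatin. The design placed these 4 profiles side by side in the same cell line, with the question of where each was enriched and how far the enriched regions coincided. There was 1 library per antibody, and all values describe these libraries.

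The libraries held 3584684 (REST), 3296354 (Ring1b), 12564624 (MCAF1) and 7947440 (H4K20me3) reads with 1 reported location. After repeated positions were removed, 3131692, 3087218, 11026878 and 7783420 reads remained. Repeated positions took 12.6% of REST reads (95% interval 12.6% to 12.7%), 6.34% of Ring1b reads (6.32% to 6.37%), 12.2% of MCAF1 reads (12.2% to 12.3%) and 2.06% of H4K20me3 reads (2.05% to 2.07%). Within a search range of 40 to 300 bp, pairs of reads on opposite strands were most frequent at an offset of 102 bp in the REST library, 111 bp in Ring1b, 79 bp in MCAF1 and 104 bp in H4K20me3. Read pairs at this offset were 3.06 times as frequent as at offsets of 500 to 1000 bp in REST, 1.45 times in Ring1b, 1.72 times in MCAF1 and 1.69 times in H4K20me3. The Ring1b curve was nearly flat, and its value of 1.448 at 111 bp was below the 1.455 at 0 bp.

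**Figure D1:**
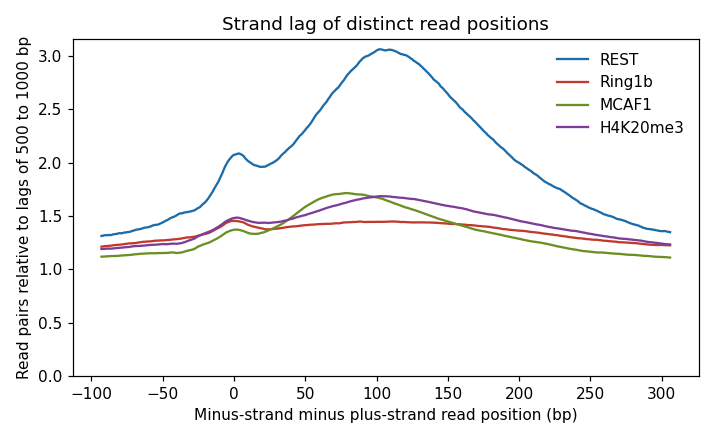
Number of read pairs on opposite strands (y axis, relative to offsets of 500 to 1000 bp) against the offset of the minus-strand from the plus-strand read in bp (x axis), with 1 line per library. REST rises to 3.06 at 102 bp, while the maxima of the other libraries within 40 to 300 bp lie between 1.45 and 1.72.

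REST regions were narrow, and the highest of them were strongly enriched. Of 2709 REST regions, the median width was 1500 bp and 12 were wider than 3 kb. Their median fold of 10.8 lay close to the 10.3-fold that an average window needed for a call. The 10 highest regions had folds between 86.1 and 157, and none of these widths exceeded 2000 bp. The highest lay on chromosome 7 at 6013501–6015000 (mm8), with 278 REST reads in its highest window, 157 times background (139 to 177), followed by chromosome 18 at 25810501–25812000 (115-fold, 98.8 to 132) and chromosome 4 at 21802501–21804000 (114-fold, 97.0 to 133). In the same windows Ring1b read density was 17.9, 9.58 and 14.4 times its background, and H4K20me3 was 1.19, 1.44 and 1.77 times. The REST regions took 2.72% of distinct REST reads (2.70% to 2.74%). With the reads of the other 3 libraries as background, 1048 REST regions were called, and the 10 highest were among those that stayed. The number of REST regions was 6001 at a probability threshold of 1e-06 and 1602 at 1e-12.

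Ring1b gave the most regions and the widest ones. It had 10580 regions, which took 21.1% of its distinct reads (21.1% to 21.2%), and 890 were wider than 3 kb. The highest regions lay on chromosome 1 at 130417501–130421000 (133-fold, 115 to 154), chromosome 3 at 45471501–45479000 (131-fold, 113 to 152) and chromosome 3 at 93528001–93534000 (124-fold, 106 to 143). The 10 highest regions were 3500 to 11000 bp wide, and in their highest windows H4K20me3 lay between 3.84 and 15.04 times background while REST lay between 0.735 and 6.61 times. With the other 3 libraries as background, 2950 Ring1b regions were called, and the 10 highest stayed.

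MCAF1 was weakly enriched despite having the deepest library. It had 2044 regions, and they took 0.957% of its distinct reads (0.952% to 0.963%). Their median fold of 5.83 lay close to the 5.01-fold that an average window needed for a call at this depth, so it cannot be ranked against the medians of other libraries. The highest region, on chromosome 5 at 138509001–138511000, reached 42.9-fold (37.7 to 48.6), and Ring1b reached 69.0-fold there (56.6 to 83.4). The next were chromosome 14 at 55191001–55192500, with 19.3-fold enrichment (16.0 to 23.1) and 0 Ring1b reads in its highest window (upper limit 2.46-fold), and chromosome 3 at 67670001–67671500 with 18.4-fold (14.7 to 22.6). With the other 3 libraries as background 41 MCAF1 regions were called, and 2 of the 10 highest stayed. When every library was thinned to 3083311 reads, 346 were called, against 2580 for REST, 10474 for Ring1b and 3109 for H4K20me3.

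H4K20me3 regions were numerous, of moderate fold and mostly narrow among reads with 1 location. There were 9463 regions with a median width of 1500 bp, and they took 5.44% of distinct reads (5.43% to 5.46%). Their median fold was 6.80, where an average window needed 5.91-fold for a call. The highest lay on chromosome 9 at 123775501–123783500 (49.9-fold, 43.8 to 56.5), chromosome 12 at 20476001–20481500 (47.0-fold, 39.96 to 54.9) and chromosome 14 at 13138501–13146000 (39.0-fold, 32.6 to 46.2). In these windows Ring1b was 5.13, 1.49 and 1.49 times its background and MCAF1 was 9.19, 5.63 and 3.75 times. With the other 3 libraries as background 1270 regions were called, and 5 of the 10 highest stayed; after thinning 3109 were called.

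Regions within 10 kb of each other were joined to see whether occupancy spread over longer stretches. Ring1b formed 429 domains longer than 10 kb, against 295 for H4K20me3, 33 for REST and 28 for MCAF1. The widest Ring1b domain covered 126.5 kb of chromosome 15 (102737501–102864000), where Ring1b read density was 45.0 times the genome mean (44.0 to 46.1), H4K20me3 2.70 times, REST 2.35 times and MCAF1 1.81 times. Ring1b domains of 123 kb on chromosome 6 (52081501–52204500) and 108 kb on chromosome 2 (74456501–74564500) had densities of 52.9 (51.8 to 54.0) and 49.8 times (48.6 to 50.9). The widest H4K20me3 domain covered 45 kb of chromosome 8 (108143001–108188000), with H4K20me3 at 5.19 times (4.84 to 5.57) and Ring1b at 11.5 times (10.7 to 12.4). A domain of 31.5 kb on chromosome 17 (6376001–6407500) was the widest for MCAF1 and overlapped the second widest H4K20me3 domain. There MCAF1 was at 9.58 times, H4K20me3 10.6, REST 10.4 and Ring1b 6.61. Merging within 5 kb lowered the numbers above 10 kb to 198 for Ring1b, 52 for H4K20me3, 5 for REST and 8 for MCAF1.

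**Figure D2:**
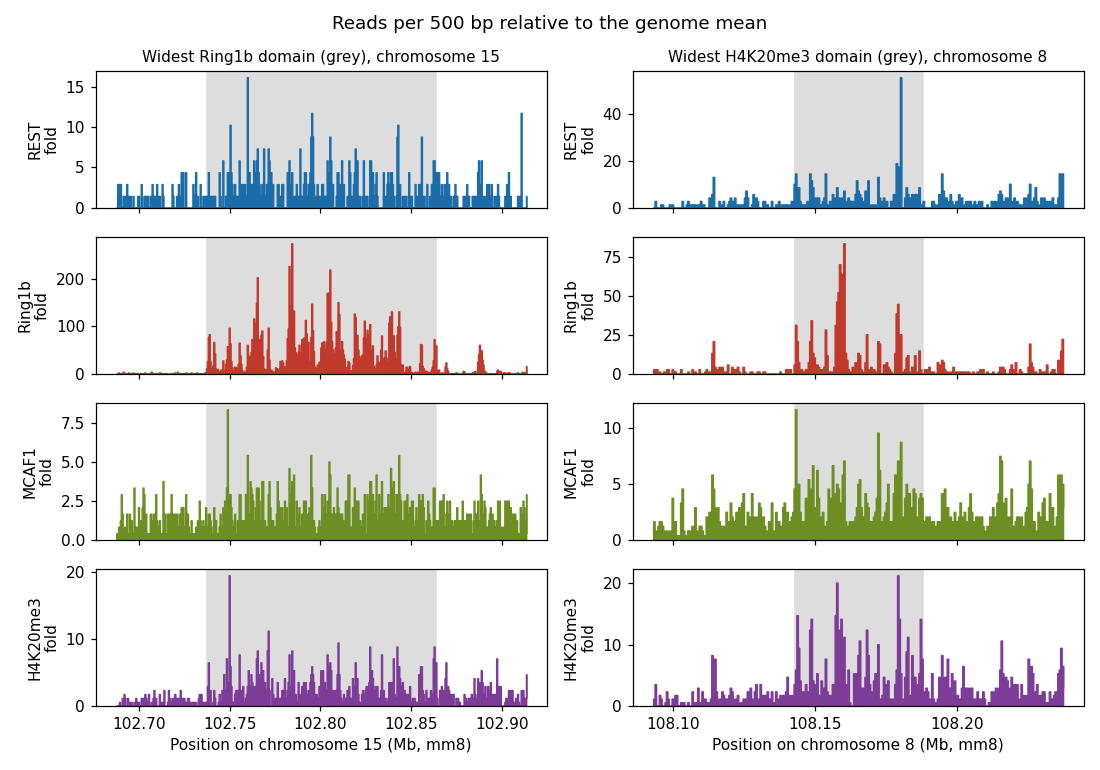
Reads per 500 bp relative to the genome mean of each library (y axis, a separate scale in each panel) along the widest Ring1b domain on chromosome 15 (left) and the widest H4K20me3 domain on chromosome 8 (right), with position in Mb of mm8 on the x axis and the domain in grey. Mean density inside the left domain is 45.0 times for Ring1b and 2.70 times for H4K20me3, and inside the right domain 11.5 and 5.19 times.

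Ring1b and H4K20me3 shared the largest number of regions. Of 10374 Ring1b regions outside those called in all 4 libraries, 4643 overlapped an H4K20me3 region (44.8%, 43.8% to 45.7%), where the circular shifts gave 119.7 on average and 441 at most. In the other direction 52.4% of H4K20me3 regions overlapped Ring1b (51.4% to 53.4%). Examples were chromosome 1 at 17081501–17084000, with 52.9-fold Ring1b (41.4 to 66.8) and 23.6-fold H4K20me3 (18.7 to 29.4), and chromosome 12 at 52514001–52516500 with 55.9-fold (44.0 to 70.1) and 23.6-fold (18.7 to 29.4). When Ring1b regions were ordered by fold over the local background and split into 3 equal groups, the share in H4K20me3 regions was 25.4% (23.9% to 26.9%), 42.05% (40.4% to 43.7%) and 66.8% (65.2% to 68.4%) from lowest to highest. Ordered by read density over the genome mean, it was 37.9% (36.3% to 39.5%), 38.9% (37.3% to 40.5%) and 57.5% (55.8% to 59.1%). In the groups by fold, median width was 1000 bp in the lowest and 2000 bp in the highest group, and the median H4K20me3 fold was 5.51 and 5.48. The overlap fell to 1845 after thinning, where 3109 H4K20me3 regions were called in place of 9463. It fell to 634 of 3837 regions with REST and MCAF1 as background. The shifts gave at most 24 there, but the selection of both region sets against the same 2 libraries largely fixed that outcome.

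REST and Ring1b coincided at many sites. Of 2504 REST regions, 930 overlapped a Ring1b region (37.1%, 35.2% to 39.1%), where the shifts gave 32.6 on average and 51 at most. From the lowest to the highest of 3 equal groups by REST fold over the local background, the share in Ring1b was 44.0% (40.6% to 47.4%), 39.6% (36.3% to 43.1%) and 27.8% (24.8% to 31.0%), the share in H4K20me3 22.2%, 29.5% and 13.2%, and the share in MCAF1 5.03%, 7.54% and 3.60%. Median REST density was 12.5 times the genome mean in the lowest group and 11.3 times in the middle group, at median widths of 1000 and 1500 bp. Ordered by density over the genome mean, the share in Ring1b was 37.0% (33.7% to 40.4%), 44.1% (40.7% to 47.5%) and 30.3% (27.2% to 33.6%), highest in the middle. Strong shared sites lay on chromosome 13 at 9010001–9012000, with 45.4-fold REST (35.0 to 58.0) and 44.7-fold Ring1b (34.1 to 57.6), and on chromosome 9 at 75469001–75470500 with 51.6-fold (41.3 to 63.9) and 31.8-fold (23.1 to 42.6). With MCAF1 and H4K20me3 as background, 72 of 1144 REST regions overlapped Ring1b. The shifts gave at most 15, an outcome that the selection against the same 2 libraries largely fixed.

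MCAF1 regions coincided with both Ring1b and H4K20me3, with Ring1b more often when each library served as its own background. Of 1847 MCAF1 regions, 43.2% overlapped H4K20me3 (40.9% to 45.5%) and 52.6% overlapped Ring1b (50.3% to 54.9%). The 798 MCAF1 regions shared with H4K20me3 compare with at most 31 in the shifts. They were 46.9 times the shift mean, against 43.5 times for the 972 shared with Ring1b, so the order of the pairs differs by this measure. Regions shared by MCAF1 and H4K20me3 included chromosome 1 at 87422001–87425000, with 16.0-fold MCAF1 (12.9 to 19.6) and 27.0-fold H4K20me3 (22.7 to 32.0). REST was 11.2-fold (6.55 to 18.0) and Ring1b 5.34-fold (2.44 to 10.1) in the same window. Another was chromosome 14 at 104991001–104993500, with 14.2-fold MCAF1 (11.0 to 18.0) and 18.0-fold H4K20me3 (13.8 to 23.1). Ring1b was 15.7-fold (9.69 to 23.9) and REST 8.08-fold (4.03 to 14.5) there. With REST and Ring1b as background, 53 of 159 MCAF1 regions overlapped H4K20me3 and the shifts gave at most 3. With REST and H4K20me3 as background 8 of 2643 Ring1b regions overlapped the 59 MCAF1 regions called there, where the shifts also gave at most 3. The selection of both sets of a pair against the same 2 libraries largely fixed these comparisons with the shifts. After thinning, 64 MCAF1 regions overlapped H4K20me3 and 149 Ring1b regions overlapped MCAF1.

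REST shared fewer regions with MCAF1 and H4K20me3 than with Ring1b, which had the largest region set. REST overlapped H4K20me3 at 541 regions (21.6%, 20.01% to 23.3%) and MCAF1 at 135 (5.39%, 4.54% to 6.35%), where the shifts gave at most 40 and 12. These counts were 22.5 and 31.3 times the shift mean, against 28.5 times for REST in Ring1b, so relative to the shifts the overlap with MCAF1 was not lower. The strongest region shared by REST and MCAF1, by the smaller of both folds, lay on chromosome 17 at 36092001–36093500 (13.9-fold and 15.4-fold). Ring1b was 8.44-fold (4.49 to 14.4) and H4K20me3 7.41-fold (4.97 to 10.6) in the same window. With the 2 outside libraries as background, 1 of 1018 REST regions overlapped H4K20me3, where the shifts gave 1.23 on average and 7 at most. Of 1009 REST regions 0 overlapped the 38 MCAF1 regions called there, where the shifts gave 0.034 on average and at most 1. With so few MCAF1 regions, that 0 says little. Of the 1048 REST regions called against the other 3 libraries, 30 overlapped H4K20me3 regions called with their own background and 8 overlapped such MCAF1 regions, where the shifts gave at most 20 and 8. After thinning the numbers with each library's own background were 244 and 38.

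**Figure D3:**
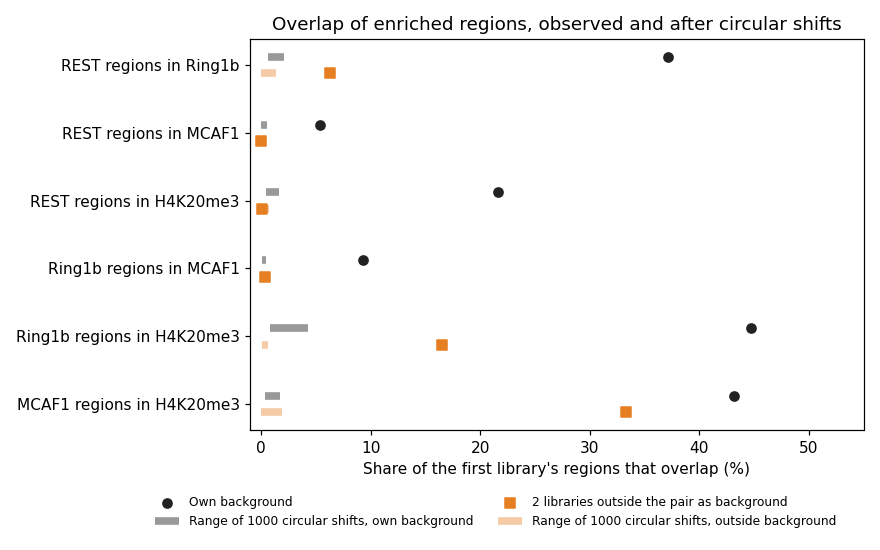
Share in percent of the first library's regions that overlap the second library's (x axis) for the 6 pairs (y axis); points are observed shares, with each library's own background (black) or with the 2 libraries outside the pair as background (orange), and bars span 1000 circular shifts. The Ring1b share in H4K20me3 moves from 44.8% to 16.5%, the MCAF1 share in H4K20me3 from 43.2% to 33.3%, and the REST share in Ring1b from 37.1% to 6.29%. For the outside background, the selection of the regions largely fixed the comparison with the shifts.

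About 200 regions per library were called in all 4 libraries (205 for REST, 206 for Ring1b, 197 for MCAF1 and 199 for H4K20me3). The highest by the smallest of the 4 folds lay on chromosome 17 at 39450501–39457500, with folds of 153 for REST (144 to 162), 158 for Ring1b (150.2 to 166), 121 for MCAF1 (114 to 129) and 147 for H4K20me3 (138 to 155). The others were on chromosome 2 at 98462501–98469000, with folds of 173, 209.4, 111 and 105, and on chromosome 5 at 2999501–3003000. With the other 3 libraries as background 3 stayed for REST, 8 for Ring1b, 0 for MCAF1 and 5 for H4K20me3.

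The reads of each library were then counted in the regions of the others, including sites below the calling threshold. Every library was enriched in the regions of every other. Summed over all regions of a set, Ring1b reads were 15.6 times as dense as the genome mean in H4K20me3 regions (15.5 to 15.6), 11.9 times in MCAF1 regions (11.7 to 11.99) and 8.47 times in REST regions (8.38 to 8.56). In Ring1b regions, H4K20me3 reads were at 5.64 times (5.62 to 5.66), REST reads at 4.95 times (4.92 to 4.97) and MCAF1 reads at 3.24 times (3.23 to 3.26). The lowest of these 12 ratios was 3.22 times for MCAF1 reads in H4K20me3 regions (3.20 to 3.23). The median per region was lower for Ring1b reads, at 8.95 times in H4K20me3 regions, 9.69 times in MCAF1 regions and 6.71 times in REST regions, and in Ring1b regions it was 5.40 times for H4K20me3, 4.90 for REST and 3.34 for MCAF1 reads. The same medians in the circular shifts stayed below 1 for all 12.

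**Figure D4:**
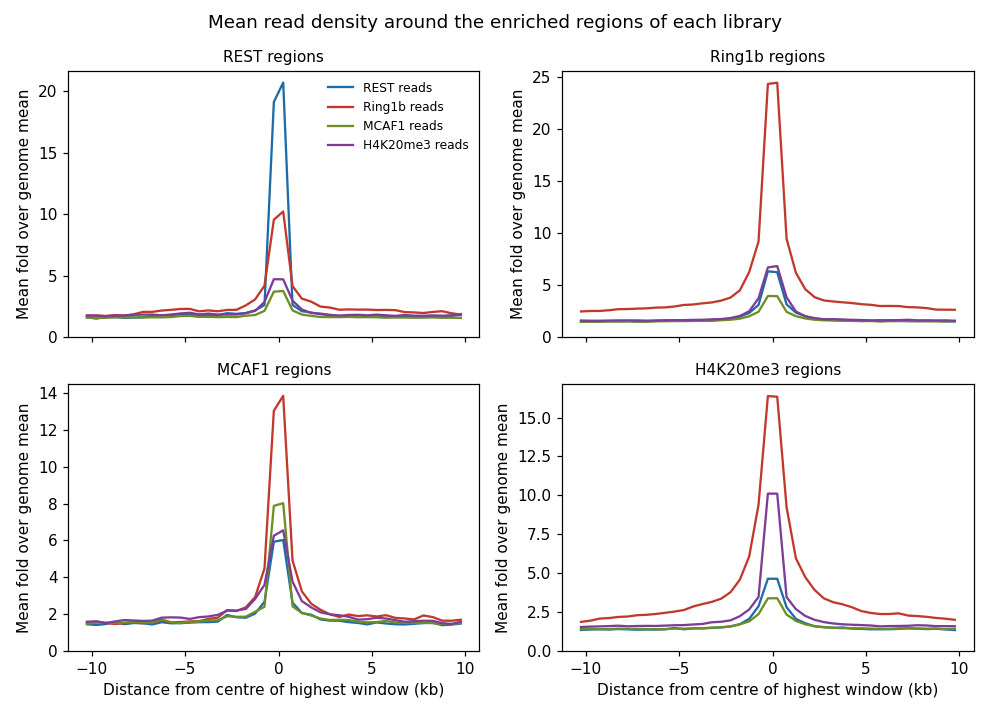
Mean read density relative to the genome mean (y axis) within 10 kb of the highest window of each library's regions (x axis, kb), with 1 panel per region set and 1 line per library of reads. In H4K20me3 regions the Ring1b line reaches 16.4 and the H4K20me3 line 10.1; in REST regions REST reaches 20.7 and Ring1b 10.2.

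Over the whole genome, MCAF1 and H4K20me3 were the most similar pair. Across 251793 bins of 10 kb their Spearman correlation was 0.904, and the remaining pairs lay between 0.774 (REST and H4K20me3) and 0.835 (Ring1b and MCAF1). With the other libraries held constant, the partial rank correlation was 0.659 for MCAF1 and H4K20me3, 0.358 for REST and MCAF1, 0.335 for Ring1b and MCAF1, 0.263 for REST and Ring1b, 0.104 for Ring1b and H4K20me3 and 0.0585 for REST and H4K20me3. MCAF1 and H4K20me3 were also the deepest libraries and those aligned with the longer seed. Thinned to the same read number, this pair's correlation was 0.817, the highest of the 6. REST and MCAF1 (0.782), Ring1b and MCAF1 (0.785) and REST and Ring1b (0.775) then lay close together. The partial values were computed at unequal depth only, and the highest all involved MCAF1, the deepest library.

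Reads were sparse on the X chromosome and dense on chromosome 11 in each library. Relative to the mean of the autosomes, X density was 0.402 for REST (0.399 to 0.405), 0.375 for Ring1b (0.372 to 0.378), 0.358 for MCAF1 (0.357 to 0.360) and 0.313 for H4K20me3 (0.311 to 0.314). Chromosome 11 lay between 1.25 and 1.33 and chromosome 8 between 1.14 and 1.20. Ring1b had 7.07 regions per Mb on chromosome 11 (6.59 to 7.58) and 1.41 on the X chromosome (1.20 to 1.65). The background was never set below the genome mean, so windows on the sparsely read X chromosome needed more enrichment over their own surroundings for a call. Copy number was not separated from chromosome preference, so a depletion of Ring1b on the X chromosome does not follow.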

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

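The values in this part are given because they came from reads that the comparisons left out, and the region calls from reads with 2 locations were chosen only after the data were examined. With no control library here, the only level to set them against was a count of 0, which any sizeable set of reads exceeds, so their presence in this part shows nothing more. Reads with 2 reported locations, called in the same way on their own, gave 471 regions for REST, 943 for Ring1b, 2579 for MCAF1 and 2821 for H4K20me3. Of these, 21.2%, 33.3%, 5.12% and 9.22% overlapped a region called from reads with 1 location in the same library. Each such read stands at both of its locations, so a region can be the copy of another.

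Mitochondrial reads numbered 3184 in REST, 5227 in Ring1b, 4517 in MCAF1 and 464 in H4K20me3. They were 0.0888% (0.0858% to 0.0920%), 0.159% (0.154% to 0.163%), 0.0360% (0.0349% to 0.0370%) and 0.00584% (0.00532% to 0.00639%) of reads with 1 location.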

How the results depend on the processing

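The addition of reads with 2 locations, the background from the 2 libraries outside a pair and the groups by density over the genome mean were alternatives chosen only after the data were examined; the others were fixed beforehand. Of 184 values under 16 alternatives, 82 stayed within 1.5 times for counts or within counting error for other values, 40 moved up and 62 moved down. Counts and folds have no sign, so a change of direction was not open to them. The 10 values without a read shift, the 10 with 2-location reads added and the 6 with a larger required overlap all stayed. The cause of a move was not tested unless the construction of the alternative gives it. The comparison of promoter lists was not run, for want of an mm8 annotation here. No paired analysis was possible because each antibody had 1 library. Depth limited the shallow libraries, where a window needed 14 reads (REST and Ring1b) for a call, and region numbers are not comparable between libraries without thinning.

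With the other 3 libraries as background, which removes what they share, there were 1048 REST, 2950 Ring1b, 41 MCAF1 and 1270 H4K20me3 regions. The median MCAF1 fold of 5.83 lay close to the minimum of 5, so a small rise of the background already removes many MCAF1 regions. With the 2 outside libraries as background, shared regions numbered 72 (REST in Ring1b), 0 (REST in MCAF1), 1 (REST in H4K20me3), 8 (Ring1b in MCAF1), 634 (Ring1b in H4K20me3) and 53 (MCAF1 in H4K20me3). At least 10-fold enrichment, a narrower definition, left 1644 REST, 152 MCAF1 and 1376 H4K20me3 regions. The pair counts, in the order just given, were then 502, 19, 103, 60, 839 and 36.

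At a probability of 1e-06 there were 6001 REST regions, of which 2926 overlapped Ring1b, 232 MCAF1 and 1484 H4K20me3; at 1e-12 the numbers were 1602, 362, 62 and 202. Windows of 2000 bp gave 427 MCAF1 and 4209 H4K20me3 regions, and overlaps of 44 (REST in MCAF1), 192 (Ring1b in MCAF1), 2591 (Ring1b in H4K20me3) and 141 (MCAF1 in H4K20me3). Windows of 500 bp gave 3465 MCAF1 regions, 215 REST regions in MCAF1, 349 in H4K20me3 and 17 REST domains above 10 kb. Joining within 5 kb, a stricter rule, gave 5 REST, 198 Ring1b, 8 MCAF1 and 52 H4K20me3 domains.

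Thinning to 3083311 reads per library, which removes reads from all but the smallest, gave 346 MCAF1 and 3109 H4K20me3 regions. Overlaps were then 38 (REST in MCAF1), 244 (REST in H4K20me3), 149 (Ring1b in MCAF1), 1845 (Ring1b in H4K20me3) and 64 (MCAF1 in H4K20me3). Genome-wide correlations after thinning were 0.782 (REST and MCAF1), 0.740 (REST and H4K20me3), 0.785 (Ring1b and MCAF1), 0.752 (Ring1b and H4K20me3) and 0.817 (MCAF1 and H4K20me3). In bins of 100 kb they were 0.941 (REST and Ring1b), 0.964 (REST and MCAF1), 0.927 (REST and H4K20me3), 0.944 (Ring1b and MCAF1), 0.918 (Ring1b and H4K20me3) and 0.970 (MCAF1 and H4K20me3).

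With all repeated positions kept, 3922 REST regions were called in place of 2709. Of the larger set, 1438 overlapped Ring1b and 869 overlapped H4K20me3. In REST regions the folds were 8.97 for Ring1b, 3.44 for MCAF1 and 4.54 for H4K20me3 reads. In Ring1b regions they were 5.03 for REST and 5.60 for H4K20me3, in MCAF1 regions 11.4 for Ring1b and 6.32 for H4K20me3, and in H4K20me3 regions 15.3 for Ring1b and 3.20 for MCAF1. Correlations were 0.771 (REST and Ring1b), 0.827 (REST and MCAF1), 0.829 (Ring1b and MCAF1) and 0.780 (Ring1b and H4K20me3).

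At 1e-12, folds in REST regions were 7.55 for Ring1b, 3.12 for MCAF1 and 3.64 for H4K20me3 reads, and in Ring1b regions 5.91 for H4K20me3. In MCAF1 regions they were 5.88 for REST, 12.6 for Ring1b and 6.91 for H4K20me3, and in H4K20me3 regions 4.63 for REST, 17.1 for Ring1b and 3.42 for MCAF1. With regions called in all 4 libraries kept, 345 REST regions overlapped MCAF1. Folds were then 11.2, 4.48 and 5.65 for Ring1b, MCAF1 and H4K20me3 reads in REST regions, and 5.37, 3.46 and 5.87 for REST, MCAF1 and H4K20me3 reads in Ring1b regions. They were 8.47, 15.04 and 7.999 for REST, Ring1b and H4K20me3 reads in MCAF1 regions, and 4.88, 16.1 and 3.53 for REST, Ring1b and MCAF1 reads in H4K20me3 regions.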

Other observations

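In this part, 7 tests were chosen only after the result was seen: the fold ratios, for 3 pairs, in reads not used for the calls, the restriction of group shares to the REST regions outside the 72, the restriction of a fold ratio to shared Ring1b and H4K20me3 regions, and the counts of identical read positions in the 72 and in the 53 regions; the same count for Ring1b and H4K20me3 and the groups by density over the genome mean were added then too. The fold ratios replaced earlier comparisons of the 634, 72 and 53 shared regions with circular shifts and with reads dealt at random between libraries, both of which the counts exceeded. Both were dropped as tests because the selection of the regions largely fixed their outcome. The values of the shifts are still given above, as description only. The flanks of the regions described first were also examined after the overlaps had been seen.

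A part of the H4K20me3 regions stood apart from the other profiles. With the other 3 libraries as background, 1214 regions outside those called in all 4 stayed, with a median H4K20me3 fold of 7.98 and median folds of 0.980 for REST, 0.746 for Ring1b and 1.53 for MCAF1; the low values of the other libraries follow in part from the selection. Within 10 kb of them, 11.2% of windows held no read of any library, against 2.17% around the H4K20me3 regions that did not stay. The median density of 2-location reads was 1.45 times the genome mean in the regions that stayed and 0.724 times in the others. The selection for few reads of the other libraries could bear on these values too. Near the ends of the assembled chromosomes, within 500 kb of the first or last window with reads, 20 of the 1270 regions called against the other 3 libraries were found where 8.88 would follow from the mean density, 2.25 times as many (1.38 to 3.48). This interval spans the bound of 2 set beforehand for a gathering at chromosome ends, so the test did not decide. With each library's own background the ratio was 1.82 (1.51 to 2.18) for H4K20me3, 4.72 (3.61 to 6.07) for MCAF1, 1.71 (1.16 to 2.45) for REST and 1.17 (0.936 to 1.45) for Ring1b. With that background an excess near the ends was therefore not particular to H4K20me3. Against the other 3 libraries the ratio was 0.410 (0.0844 to 1.20) for REST and 0.679 (0.371 to 1.14) for Ring1b, so only H4K20me3 lay above 1 there. For MCAF1 none of the 41 regions called against the other libraries lay near the ends, where 0.287 would follow from the mean density, too few to tell.

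Regions called in all 4 libraries had a median density of 2-location reads 1.964 times that of the other Ring1b regions, between the bounds of 1 and 3 set beforehand for ruling out or accepting sequence with more copies than the assembly holds. The means lay further apart, at 57.2 and 1.961 times the genome mean, and the share with more than 3 times the mean 2-location density was 38.3%, against 9.74% of the other Ring1b regions. Reads from copies that the assembly lacks can be placed at 1 held copy and then count as reads with 1 location. The density of 2-location reads misses these, so it can neither accept nor rule out extra copies. They were left undecided for the set as a whole.

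The overlap of Ring1b with H4K20me3 was weighed in 2 parts. With REST and MCAF1 as background 634 shared regions stayed. From 1 random part of the reads 937 shared regions were called, which took in 464 of these. In the other part their median H4K20me3 fold was 2.73 times that of REST and MCAF1 (2.60 to 2.82, lower quartile 2.03), the lowest median over both libraries and both parts. Their median Ring1b fold was 9.18 times that of REST and MCAF1 (8.57 to 9.56, lower quartile 5.16). A background of equal strength in all 4 libraries was taken to predict 0.67 to 1.5, and these values lie above that range. The H4K20me3 ratio did not reach the bound of 3 set for excluding such a background, so the test stayed undecided. Both parts came from the same libraries, so a deviation of 1 library that favoured the selection would recur in both. Identical read positions were 1.08 times as frequent as positions at neighbouring offsets, the lowest of the 6 pairs. The 2 pairs with equal alignment seeds had the highest ratios (1.29 and 1.22). Reads of unequal length might match on 1 strand only, so this rank cannot decide on carried molecules. In all 4643 shared regions identical positions exceeded those at neighbouring offsets by 414 (265 to 566), where 15553 would follow if the reads of 1 library were molecules of the other. This gap is wider than the loss of 1 strand would make, which argues against carried molecules as the whole cause. For the 4010 shared regions outside that part, the median ratio of the H4K20me3 fold to the mean of the REST and MCAF1 folds was 1.72 (quartiles 1.31 and 2.23), between the bounds of 1.5 and 3; over all 9740 Ring1b regions outside it, the set for which the test was first written, it was 1.25, inside the range of 0.67 to 1.5 that such a background predicts, so this part cannot be told apart from it. A background stronger in the Ring1b and H4K20me3 libraries than in the rest stays open without an input library, and occupancy by both Ring1b and H4K20me3 is a candidate explanation for the 634 regions that was not tested apart from these alternatives.

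For the overlap of REST with Ring1b, 72 shared regions stayed with MCAF1 and H4K20me3 as background. They were tested in the same way through 129 regions that took in 60 of them. In reads not used for the calls, the lowest median ratio to MCAF1 and H4K20me3 was 4.17 (3.66 to 4.58, for Ring1b), above the bound of 3. This argues against a background of equal strength in all 4 libraries for the 129 regions. Here too, a deviation of 1 library that favoured the selection would recur in both parts. The 72 regions had median folds of 19.1 for REST and 16.5 for Ring1b. The REST and Ring1b reads were aligned with the shorter seed, and 2-location read density in these regions was 1.75 times that in the other REST regions, between the bounds of 1 and 3, so placement of repeated sequence cannot be told apart from shared occupancy. Nor can molecules carried from 1 library into the other, since identical read positions in the 72 regions exceeded those at neighbouring offsets by 164 (132 to 198), where 360.4 would follow if all were carried, and were 1.22 times as frequent over all regions of either library. Over the 2432 REST regions outside that part, the share in Ring1b was 21.3 percentage points higher in the lowest than in the highest group by fold over the local background but 9.34 points higher by density over the genome mean (16.1 and 6.67 over all 2504 regions, the set for which the test was first written), on different sides of the bound of 10, so a background common to all 4 libraries was left undecided. Binding of both proteins at the 72 sites is an open and untested alternative.

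For the overlap of MCAF1 with H4K20me3, 53 shared regions stayed with REST and Ring1b as background. They were tested in the same way through 81 regions that took in 40 of them. In reads not used for the calls, the lowest median ratio to REST and Ring1b was 3.38, for MCAF1 (2.96 to 4.13, lower quartile 2.07). The H4K20me3 median in the same reads was 4.79 (3.19 to 6.78, lower quartile 2.59). A background of equal strength in all 4 libraries was taken to predict 0.67 to 1.5, and these values lie above that range. The MCAF1 interval spans the bound of 3 set for excluding such a background, so the test stayed undecided. Again, a deviation of 1 library that favoured the selection would recur in both parts. Reads of REST and Ring1b pooled had a median fold of 0.925 in the 53 regions (quartiles 0.740 and 1.48), above the bound of 0.5. This argues against sites that only the longer seed could map. A partial loss of reads with the shorter seed would not show in this test and stays open. Identical read positions were 1.29 times as frequent as at neighbouring offsets over all regions of either library, the highest of the 6 pairs, though only this pair and REST with Ring1b had equal alignment seeds. In the 53 regions they exceeded those at neighbouring offsets by 31.1 (13.4 to 51.8), where 92.5 would follow if all were carried. Molecules carried from 1 library into the other therefore cannot be told apart from shared occupancy. The median 2-location read density there was 5.07 times the mean, and repeated sequence, a background stronger in these libraries and differences between sequencing runs stay open. Shared occupancy of MCAF1 and H4K20me3 may account for the 53 regions, as a hypothesis that these data did not test.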
